A study of Homo sapiens with 36 samples.

How the data were processed

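Gene expression was measured by sequencing of poly(A) RNA, with directional library preparation, in 36 libraries from i3Neurons at day 14. Per the labels the first shRNA, control or against TDP-43, was given for 8 days and the second, control or against DCPS, for 6 days. Actinomycin D is labelled at 5 µg/µL for 0, 3 and 6 h. Libraries were grouped by the labels into 12 groups of 3, with 9 steady-state libraries in one batch and 27 decay libraries in another, so the experiments were tested separately and compared only as results.

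The authors' notes name Trim Galore 0.6.7, HISAT2 2.2.1, Subread 2.0.1 and DESeq2, and the build GRCh38. Which settings, and which strand setting for counting, are not given in the sources used here. The deposited steady-state table holds raw counts per gene and library, whole numbers with 18.0 to 22.7 M (1e6) reads a library. The deposited decay table holds values in another unit, a signal that the authors normalized by a method not given in the sources used here. Tested against gene length, each library's values equalled a constant times reads per base to a power of 1.04 to 1.18 that differed between libraries. They are therefore neither TPM nor counts divided by a size factor, and column sums ran from 39909 to 181216. Inverting the relation gave whole reads within 0.05 for 100% of the values up to 300 reads and for at least 95.0% of all values in every library, with 6.93 to 11.8 M reads a library. These recovered reads were rounded and used as an alternative chosen after the data were seen. On the deposited scale constant and power cannot be separated from changes in total RNA, so the main tests keep that scale and changes relative to other genes come from recovered reads.

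Both tables listed 60648 genes after 1 gene, ANK2, was left out, whose line was broken in both (3 broken lines in the steady-state table and 5 in the decay table). A symbol was found for 60462 of them (99.7%), 1267 of which share a symbol with another gene, and lists were matched by symbol. No spike-in RNA was among the rows. XIST and Y-linked genes were left out of the named genes. A few genes that the naming rule selects are not reported here.

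Steady-state counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr by group, quasi-likelihood F test) in a single fit of the 9 libraries, so 3 contrasts shared an estimate of the spread. Values at 0 h were tested with limma 3.58.1 (limma-trend) on log2 of the deposited value plus 1, for genes with a mean of at least 10. Decay was tested by the slope of the same log2 values per hour in each genotype and by differences between slopes, across all 27 libraries. A half-life is 1 over the size of the median slope, and so depends on the 1 added to the values. All p-values were Benjamini-Hochberg adjusted over the genes of a contrast, and genes passed at an adjusted p under 0.05. Recovered reads were tested with edgeR in the same designs. Differences and slopes are given as log2 values with standard errors, and levels as CPM with SD over 3 libraries.

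There were 28 gene lists fixed before the data were examined: knockdown targets, TDP-43 cryptic splicing targets, P-body and decapping, deadenylation, exosome and 3-prime decay, nonsense-mediated decay, cap binding and cap synthesis, stress granule, hnRNP and splicing factors, synaptic vesicle and release, postsynaptic receptors and scaffolds, voltage-gated channels, neuronal cytoskeleton and axon, p53 targets, integrated stress and unfolded protein response, heat shock and proteostasis, immediate-early genes, interferon response, cholesterol synthesis, glycolysis, nuclear-encoded respiratory chain, mitochondrially encoded mRNAs, ribosomal proteins, short-lived mRNAs, long-lived housekeeping mRNAs, proliferating and progenitor cell markers, glial markers, and fibroblast and mesenchymal markers. All but the knockdown targets, 27 lists, were tested with camera at a preset correlation of 0.01 and at an estimated correlation, and with fry. Values were adjusted over the lists of a contrast. Some genes stand in more than one list.

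Named genes followed a rule also fixed before the data were examined. Besides TARDBP and DCPS, it took the 8 called genes with the largest rise and the 8 with the largest fall of each steady-state contrast, among named genes with an average of at least 3 log2 CPM and no overlap between groups, and the same genes at 0 h. For slopes it took the 6 largest positive and the 6 largest negative among genes with a mean of at least 100 or 3 log2 CPM. From each list it took up to 4 called members (3 for slopes) with the smallest adjusted p, of which up to 2 were printed where the list held over 4. Others are named as singled out.

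Whether TDP43_KD changes moved back was measured as the share of opposite signs, with calls and signs from different experiments, an exact permutation of the 6 labels at 0 h, and simulated no-effect values within the steady state. Single values of groups were compared with two-sided exact permutation tests. Genes across which correlations were computed are not independent replicates.

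The tests were tried on simulated data made from the same libraries, with 100 genes changed by a known fold. All simulated genes had the same dispersion, and on the deposited scale all libraries had the same constant and power. The shares found therefore leave out differences in spread between genes and in scale between libraries. Of those changed 2-fold edgeR on the steady state found 84%, limma at 0 h 88%, and slopes 99% on the deposited scale and 100% on recovered reads. Of those changed 1.5-fold it found 58%, 49%, 35% and 45%. For slopes the fold is the difference in level reached at 6 h, not a fold change of the decay rate. No replicate block entered the main tests.

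Alternatives planned beforehand were other size factors or quantile normalization, no filter or a mean of at least 50, a pseudocount of 5, DESeq2 1.42.0, a replicate block, the 2 groups alone, a minimum effect, 6 h against 0 h, scaling to the long-lived housekeeping list, and leaving out each library. Tests on recovered reads, with the power set to 1, and of the mitochondrial list without the 0 h library with the highest share of mitochondrial reads were added after the data were seen. DESeq2 was not run on the deposited decay values, which are not counts, but on recovered reads. Other splits of the libraries were fitted with the 2 genotypes compared. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9.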

Results

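Polyadenylated RNA was sequenced from human i3Neurons, neurons made from an established line of induced pluripotent stem cells, at day 14. The neurons had received 2 shRNAs in turn, the first for 8 days and the second for 6 days. In the control group both were non-targeting, in TDP43_KD the first targeted TDP-43 (gene TARDBP), and in TDP43_DCPS_KD the second also targeted DCPS, a scavenger enzyme that hydrolyses the cap left after 3-prime mRNA decay. The 36 libraries formed 12 groups of 3 (n = 3 for every group below). A steady-state experiment held 9 libraries, 3 per genotype, and a decay experiment, in another batch, held 27 libraries of the same genotypes after 0, 3 and 6 h of actinomycin D, an inhibitor of transcription. DCPS knockdown was measured here on top of TDP-43 knockdown only.

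The steady-state libraries held 18.2, 22.1 and 21.9 M (1e6) counted reads in control, 19.7, 22.7 and 20.4 M in TDP43_KD, and 18.0, 20.8 and 18.4 M in TDP43_DCPS_KD. The decay libraries held 6.93 to 11.8 M reads each, recovered from the deposited values. Their group means at 0 h were 8.77 M in control, 9.85 M in TDP43_KD and 11.2 M in TDP43_DCPS_KD. Averaged over genes, counts between replicates varied 2.201 to 21.16 times as much as counting error alone gives (chi-square per degree of freedom). Single genes were not examined in this way. Whether replicates were separate cultures is not stated, so p-values measure the spread between these libraries. Positions are on GRCh38, and identifiers are Ensembl's.

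Both targets were lower wherever their shRNA was used. TARDBP (ENSG00000120948.19, chromosome 1, 11012344 to 11030528), which encodes TDP-43, an RNA-binding protein that represses cryptic exons, stood at 217, 235 and 245 CPM (counts per 1e6 reads) in the steady-state control libraries, at 31.8, 33.4 and 34.8 CPM in TDP43_KD and at 38.5, 40.6 and 37.3 CPM in TDP43_DCPS_KD. It was 6.97-fold lower in TDP43_KD than in control (log2 -2.80 ± 0.06 SE, edgeR adjusted p = 1.78e-17). In the double knockdown it stood 0.22 ± 0.07 log2 above TDP43_KD (adjusted p = 0.0111). DCPS (ENSG00000110063.10, chromosome 11, 126304060 to 126350005) stood at 19.4, 19.6 and 18.2 CPM in control and at 13.4, 14.6 and 14.1 CPM in TDP43_KD, a log2 difference of -0.44 ± 0.11 (adjusted p = 0.00155) without any shRNA against it. It stood at 3.59, 3.70 and 4.70 CPM in TDP43_DCPS_KD, a log2 difference of -1.81 ± 0.13 from TDP43_KD (adjusted p = 9.72e-10) and of -2.25 from control.

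In the decay libraries, in CPM of recovered reads, TARDBP measured 157, 173 and 187 in control at 0 h, 248, 193 and 244 at 3 h, and 248, 246 and 249 at 6 h. In TDP43_KD it measured 22.3, 23.2 and 19.96 at 0 h, 12.5, 14.2 and 11.9 at 3 h, and 14.5, 14.0 and 12.6 at 6 h. In TDP43_DCPS_KD it measured 24.6, 24.2 and 25.3 at 0 h, 13.0, 12.6 and 10.7 at 3 h, and 14.8, 17.2 and 12.2 at 6 h. DCPS measured 18.1, 16.1 and 15.5 CPM in control at 0 h, 10.8, 9.59 and 12.3 at 3 h, and 8.27, 9.12 and 8.59 at 6 h. In TDP43_KD it measured 12.2, 13.3 and 13.6 at 0 h, 13.2, 14.2 and 13.0 at 3 h, and 10.8, 10.3 and 11.2 at 6 h. In TDP43_DCPS_KD it measured 4.40, 5.34 and 4.95 at 0 h, 1.83, 3.02 and 1.82 at 3 h, and 3.90, 3.12 and 2.94 at 6 h.

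**Figure D1:**
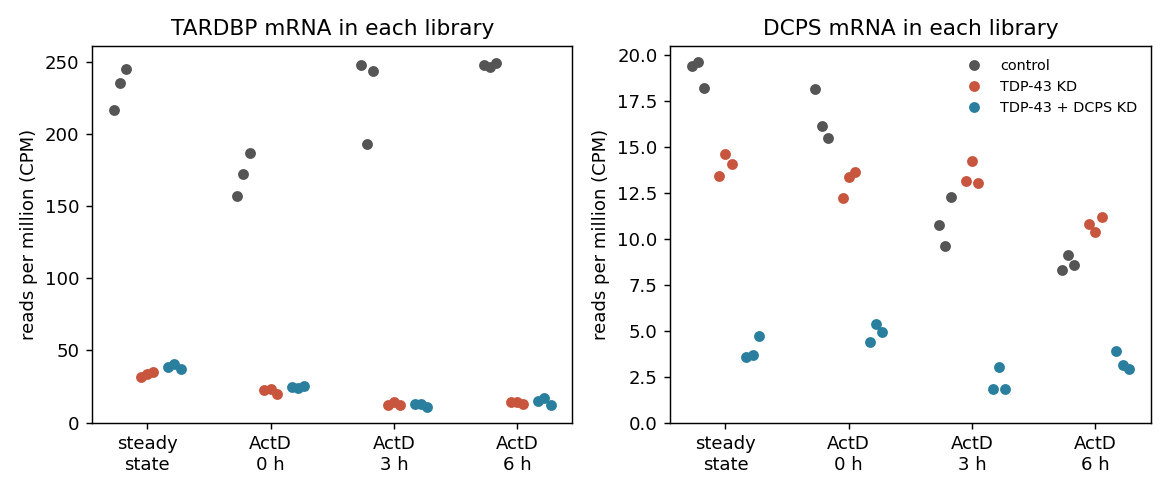
CPM of TARDBP and DCPS in each of the 36 libraries, by group, with 1 point per library. TARDBP lay between 31.8 and 40.6 CPM in the 6 steady-state knockdown libraries against 217 to 245 CPM in control, and DCPS lay between 3.59 and 4.70 CPM in the steady-state double knockdown.

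The first comparison asked what loss of TDP-43 did to steady-state mRNA levels. The mRNAs of STMN2 and ELAVL3, which TDP-43 is known to protect from cryptic splicing, fell deeply. STMN2 (ENSG00000104435.14, chromosome 8, 79611117 to 79666158), a microtubule regulator needed for axon regrowth, went from 2820 ± 155 to 515 ± 36.5 CPM (SD, n = 3), and ELAVL3 (ENSG00000196361.10, chromosome 19, 11451326 to 11481046), a neuronal RNA-binding protein, from 500 ± 25.4 to 110 ± 1.40 CPM. CDKN1A (ENSG00000124762.14), the cell cycle inhibitor p21, went from 6.83 ± 3.22 to 63.2 ± 6.31 CPM. Of 18881 genes tested with edgeR, 11761 passed (5986 higher, 5775 lower), of which 4044 differed by 2-fold or more (2202 higher, 1842 lower).

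The largest rises among genes above 3 log2 CPM, each with no overlap between the groups, included REST (ENSG00000084093.19), the repressor of neuronal genes (log2 4.65 ± 0.20 SE), MVP (ENSG00000013364.19), the major vault protein (4.50 ± 0.10), EHD2, a caveola-associated ATPase (4.18 ± 0.19), LIN28A, an RNA-binding protein of stem cells (4.15 ± 0.15), ADGRG5, an adhesion receptor (4.09 ± 0.22), COL9A2, a collagen chain (3.81 ± 0.27), and FKBP10, a collagen chaperone (3.58 ± 0.08). REST rose from 0.747 ± 0.313 to 19.2 ± 0.617 CPM and MVP from 3.95 ± 0.546 to 89.1 ± 5.01 CPM. The largest falls included histone genes, H3C6 (ENSG00000274750.3, -6.65 ± 0.29), H2AC6 (ENSG00000180573.10, -5.98 ± 0.16), H2BC21 (-4.26 ± 0.09) and the pseudogene H2BC20P (-3.87 ± 0.14). H2AC6 went from 68.0 ± 9.07 to 1.08 ± 0.323 CPM. Histone genes have close paralogs, so reads may be shared among them. Poly(A) RNA was sequenced, so histone RNA without a poly(A) tail was not measured and these falls cover polyadenylated transcripts only. The other large falls were in HTATSF1 (ENSG00000102241.12), a splicing and elongation factor (-4.29 ± 0.08, from 281 ± 2.33 to 14.4 ± 1.53 CPM), NELL1, a secreted signalling protein (-3.92 ± 0.16), GALR1, a galanin receptor (-3.59 ± 0.15), and SEMA3D, an axon guidance cue (-3.55 ± 0.14). The edgeR adjusted p of these genes ran from 1.69e-18 for HTATSF1 to 3.02e-10 for COL9A2.

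Of 27 gene lists fixed before the data were examined, 8 passed the set test camera with its preset correlation of 0.01, which compares a list with the other genes. With an estimated correlation none passed (adjusted p 0.162 or more), and 3 lists had an unadjusted p under 0.05. The set test fry asks whether the genes of a list move, on balance, one way, or in its mixed form in either direction, without comparing them with other genes. It called 21 of the 27 lists, and 27 in its mixed form.

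Among the cryptic splicing targets 20 of 25 fell and 3 rose (median log2 -0.71, camera adjusted p = 1.11e-12, 0.163 with an estimated correlation). STMN2 (-2.45 ± 0.06) and ELAVL3 (-2.19 ± 0.05) had 2 of the smallest p-values, and the 3 that rose, singled out after their values were seen, were GPSM2 (1.01), EPB41L4A (0.46) and G3BP1 (0.24). The list was drawn from published work on such cells and measures gene totals, not splicing. In the list of the neuronal cytoskeleton and axon 21 of 28 fell and 2 rose (median -0.47, adjusted p = 1.91e-05, 0.296 with an estimated correlation), among them the kinesin motor KIF5B (-1.47 ± 0.05) and the neurofilament gene INA (-1.14 ± 0.04, from 2888 ± 65.6 to 1312 ± 24.9 CPM). Of 34 synaptic vesicle genes 23 fell and 6 rose (median -0.26, adjusted p = 0.00675, 0.231 with an estimated correlation). SLC17A7, a vesicular glutamate transporter, rose (1.22 ± 0.05). Of 27 postsynaptic genes 15 fell and 8 rose (adjusted p = 0.0812), with GRIA3 (-1.48 ± 0.07) and GPHN (-1.17 ± 0.07) among those that fell. Of 25 voltage-gated channel genes 14 fell and 4 rose (adjusted p = 0.0551), with SCN9A (-1.41 ± 0.07) and KCND3 (-2.15 ± 0.13) falling.

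Of 21 p53 targets 18 rose and 2 fell (median 0.86, adjusted p = 4.94e-07, 0.162 with an estimated correlation), with CDKN1A (3.18 ± 0.16) and the nuclease gene AEN (2.22 ± 0.09) among those that rose. All but 1 of the 13 mitochondrially encoded mRNAs fell (median -0.43, adjusted p = 0.000729, 0.467 with an estimated correlation), most of all MT-ATP8 (-1.37 ± 0.06) and MT-ATP6 (-1.36 ± 0.06), while of 34 nuclear-encoded respiratory chain genes 13 rose and 14 fell (adjusted p = 0.516), with ATP5F1B (-0.91 ± 0.05) and NDUFA9 (-1.19 ± 0.09) falling. Progenitor and proliferation markers rose in 6 of 13 and fell in 2 (median 0.73, adjusted p = 0.0313, 0.466 with an estimated correlation), LIN28A and the intermediate filament gene NES (0.86 ± 0.06, from 183 ± 15.1 to 333 ± 9.15 CPM) among them, while the mitotic genes CCNA2 and PLK1 fell. Of 11 glial markers 4 rose and 4 fell (adjusted p = 0.889), with MBP at -1.84 ± 0.12 and SLC1A2 at 0.31 ± 0.05, and of 9 fibroblast markers 5 rose and 2 fell (adjusted p = 0.162), with FBN1 (1.29 ± 0.09) and COL6A2 (2.52 ± 0.19) rising.

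The lists of RNA decay machinery moved in both directions. Of 25 P-body and decapping genes 7 rose and 6 fell (adjusted p = 0.758). The decapping activator EDC3 fell (-1.04 ± 0.06), as did the antiviral factor ZC3HAV1 (-2.56 ± 0.19). Of 20 deadenylation genes 11 fell and 5 rose (adjusted p = 0.0812), with the poly(A)-binding protein gene PABPC1 (ENSG00000070756.17) at -1.57 ± 0.05 (542 ± 14.9 to 182 ± 5.66 CPM) and PABPC4 at -1.46 ± 0.06. Of 21 exosome and 3-prime decay genes 7 fell and 5 rose (adjusted p = 0.758), with HBS1L at -1.05 ± 0.07 and MTREX at -0.81 ± 0.06. Of 15 nonsense-mediated decay genes 7 rose and 4 fell (adjusted p = 0.388), with SMG9 at 0.81 ± 0.06 and EIF4A3 at 0.49 ± 0.06. Of 16 cap genes 7 fell and 4 rose (adjusted p = 0.148), with NCBP3 at -0.98 ± 0.05 and EIF4E3 at -1.16 ± 0.07. Of 15 stress granule genes 8 fell and 4 rose (adjusted p = 0.0551), UBAP2L falling by 1.09 on the log2 scale. Of 33 genes of hnRNPs and splicing factors 21 fell and 4 rose (median -0.23, adjusted p = 0.0161, 0.466 with an estimated correlation), with CELF2 at -1.20 ± 0.05 and ELAVL4 at -0.95 ± 0.05.

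Among the stress lists, 8 of 25 genes of the integrated stress and unfolded protein response rose and 7 fell (adjusted p = 0.758), with the chaperone gene HSP90B1 (ENSG00000166598.16) at -1.63 ± 0.08 and PPP1R15A at -1.39 ± 0.08. Of 16 heat shock genes 10 rose and 3 fell (adjusted p = 0.0812), with BAG3 at 1.77 ± 0.09 and DNAJA1 at -1.12 ± 0.05. Of 15 immediate-early genes 7 rose and 6 fell (adjusted p = 0.636), with JUN at 1.47 ± 0.09 and FOSL2 at 2.69 ± 0.17, and of 15 interferon response genes 5 rose and 4 fell (adjusted p = 0.401), with ISG15 at 1.14 ± 0.20. Of 24 cholesterol synthesis genes 12 fell and 6 rose (adjusted p = 0.302), with SREBF2 at -0.92 ± 0.05 and MVD at -1.36 ± 0.10. Of 19 glycolysis genes 9 fell and 6 rose (adjusted p = 0.764), with HK1 at -0.82 ± 0.05 and LDHA rising from 144 to 289 CPM. Of 75 ribosomal protein genes 41 rose and 20 fell (median 0.25, adjusted p = 0.386), the fall being deepest in RPL14 (ENSG00000188846.14, -3.07 ± 0.06, from 379 ± 24.3 to 45.1 ± 1.03 CPM). Of 25 short-lived mRNAs 11 rose and 9 fell (adjusted p = 0.519), with SOX11 at -1.21 ± 0.05 and BTG2 at 1.76 ± 0.10. Of 25 long-lived mRNAs 13 fell and 6 rose (median -0.19, adjusted p = 0.0392, 0.466 with an estimated correlation), with CALM3 at -2.42 ± 0.05 and ACTB at -1.11 ± 0.05.

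Adjusted over the list alone, the counts were those given, except that 5 stress granule genes, 5 channel genes and 42 ribosomal protein genes rose and that 22 hnRNP and 8 stress response genes fell. Median, mean and camera direction differed in sign for the P-body, exosome, cap, stress response, glycolysis and glial lists, none of which passed. Counting did not state a strand setting, so overlapping antisense genes may share reads.

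**Figure D2:**
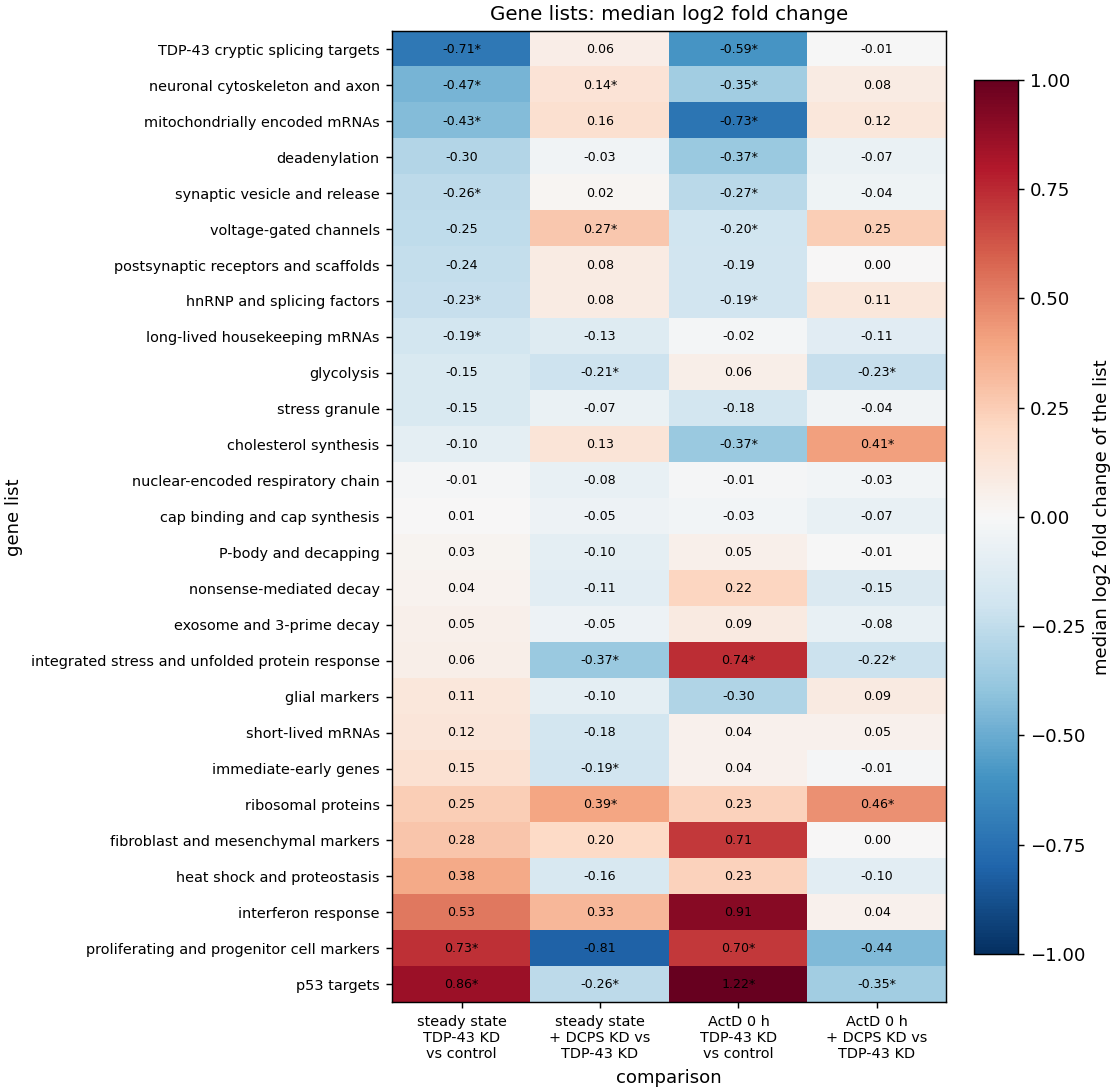
Median log2 fold change of each fixed gene list, TDP43_KD against control and TDP43_DCPS_KD against TDP43_KD, in the steady state and at 0 h on recovered reads. Stars mark lists that passed camera at the preset correlation. In the steady state cryptic splicing targets are at -0.71 in TDP43_KD against control, and ribosomal protein genes at 0.39 in TDP43_DCPS_KD against TDP43_KD.

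The second comparison asked what DCPS knockdown changed in neurons that had lost TDP-43. Of 75 ribosomal protein mRNAs 60 rose and 2 fell, and the mRNA of the poly(A)-binding protein PABPC1 returned from 182 ± 5.66 to 527 ± 12.9 CPM, against 542 ± 14.9 CPM in control. Several p53 targets, stress response genes and glycolysis genes fell. STMN2 and ELAVL3 stayed at 554 ± 30.9 and 103 ± 3.70 CPM, close to their values in TDP43_KD. Of 18881 genes 7843 passed in edgeR (3963 higher, 3880 lower), of which 1293 differed by 2-fold or more (787 higher, 506 lower).

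The largest rises were in ECEL1 (ENSG00000171551.12), a neuronal peptidase (log2 3.03 ± 0.13, from 4.25 ± 0.492 to 34.8 ± 4.65 CPM), HTATSF1 (2.81 ± 0.08, from 14.4 ± 1.53 to 101 ± 8.69 CPM), SPARC (ENSG00000113140.11), a matrix protein (2.73 ± 0.17), the guidance cues SEMA3E (2.68 ± 0.08) and SEMA3D (2.33 ± 0.14), FSTL5 (2.52 ± 0.09), the transcription regulator LMO3 (2.31 ± 0.10) and ANXA5, a phospholipid-binding protein (2.26 ± 0.15). The largest falls were in ADAM12 (ENSG00000148848.15), a metalloprotease (-3.02 ± 0.11, from 88.1 ± 7.22 to 10.9 ± 0.748 CPM), CD36 (ENSG00000135218.19), a fatty acid receptor (-2.98 ± 0.13), the collagen gene COL27A1 (-2.95 ± 0.18), the transcription factor ETV4 (-2.65 ± 0.09), TNR, a matrix glycoprotein of the nervous system (-2.37 ± 0.10), the cyclin gene CCND2 (-2.26 ± 0.08), OGFR, an opioid growth factor receptor (-2.16 ± 0.11), and POLR3K, a subunit of RNA polymerase III (-2.10 ± 0.12). Their edgeR adjusted p ran from 3.93e-15 for HTATSF1 to 6.64e-10 for ANXA5.

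The list test camera called 7 of 27 lists. Ribosomal protein genes rose (median log2 0.39, adjusted p = 1.16e-21, 0.36 with an estimated correlation, 63 rising and 2 falling when adjusted over the list alone), with RPS3A (ENSG00000145425.10) at 1.36 ± 0.05 (142 ± 5.61 to 363 ± 21.9 CPM) and RPL10 at 1.11 ± 0.05, while RPS20 and RPS26, singled out after their values were seen, fell. Ribosomal protein genes have many pseudogenes with which reads may be shared. Of 25 voltage-gated channel genes 16 rose and 5 fell (median 0.27, adjusted p = 0.011, 0.36 with an estimated correlation, 17 and 6 over the list alone), with CACNA2D1 at 0.65 ± 0.05 and KCND3 at 1.26 ± 0.13. Of 28 cytoskeleton genes 13 rose and 5 fell (median 0.14, adjusted p = 0.0232, 0.579 with an estimated correlation), with the growth cone gene GAP43 rising from 812 ± 10.4 to 1623 ± 56.3 CPM and the neurofilament gene NEFM at -0.59 ± 0.04. Of 19 glycolysis genes 10 fell and 1 rose (median -0.21, adjusted p = 0.00657, 0.36 with an estimated correlation), with PGAM1 at -0.80 ± 0.05 and ENO1 at -0.56 ± 0.04. Of 21 p53 targets 10 fell and 2 rose (median -0.26, adjusted p = 0.00687, 0.36 with an estimated correlation), with AEN at -1.56 ± 0.08 and BBC3, a death gene, at -1.28 ± 0.12. CDKN1A was 1 of those that rose, to 93.2 ± 1.75 CPM. Of 25 genes of the integrated stress and unfolded protein response 10 fell and 1 rose (median -0.37, adjusted p = 0.0486, 0.815 with an estimated correlation), with TRIB3 at -1.40 ± 0.14 and ATF4 at -0.57 ± 0.06. Of 15 immediate-early genes 6 fell and 2 rose (median -0.19, adjusted p = 0.0486, 0.417 with an estimated correlation, 8 and 3 over the list alone), with NR4A3 at -1.86 ± 0.13 and ARC at 1.35 ± 0.15.

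Among lists that did not pass, 8 of 25 P-body and decapping genes fell and 3 rose (adjusted p = 0.176, 9 and 3 over the list alone). LSM7, a subunit of the decapping activator ring, stood at -0.81 ± 0.06 and the P-body helicase gene DDX6 (ENSG00000110367.13) at -0.40 ± 0.06 (167 ± 5.22 to 127 ± 4.65 CPM, against 229 ± 13.7 CPM in control). Of 15 nonsense-mediated decay genes 5 fell and 1 rose (adjusted p = 0.0597), with SMG5 at -0.70 ± 0.06. Of 24 cholesterol synthesis genes 10 rose and 2 fell (adjusted p = 0.139), with SREBF2 at 0.51 ± 0.05, and 7 of 13 mitochondrially encoded mRNAs rose (adjusted p = 0.176). Of 25 cryptic splicing targets 8 rose and 4 fell (adjusted p = 0.403, 9 and 4 over the list alone), with NUP188 at 0.50 ± 0.07 and CYFIP2 at -0.37 ± 0.05. With an estimated correlation none of the 27 lists passed (2 with an unadjusted p under 0.05), fry called 14, and median, mean and camera direction differed in sign for the deadenylation, exosome, cap, stress granule, synaptic vesicle and glial lists.

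Whether changes of TDP43_KD moved back in TDP43_DCPS_KD was asked with calls from the steady-state libraries and signs from the separate 0 h libraries, since a shared TDP43_KD group gives opposite signs by construction. Of 1268 genes called in the steady state and measured on the deposited scale at 0 h, 794 (62.6%) had the opposite sign in TDP43_DCPS_KD against TDP43_KD. This share was uneven, 708 of 762 fallen genes (92.9%) and 86 of 506 risen genes (17.0%), because the median of all genes was 0.48 log2 higher in TDP43_DCPS_KD on that scale. With that median removed it was 65.9%. An exact permutation of the 6 library labels gave a one-sided p of 0.05 and a two-sided p of 0.10, the smallest that 20 arrangements allow, and the highest other arrangement gave 62.4%. With edgeR on recovered reads 7393 of 11022 genes (67.1%) were opposite, and with the experiments exchanged 72.0% were. The exact permutation on recovered reads gave 67.2% for the real labels and 66.5% for the highest other arrangement (two-sided p = 0.10). Arrangements that exchange only some of the libraries keep part of the real difference. On either scale the highest other share is therefore not what chance alone gives.

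Within the steady-state experiment 2307 genes fell in TDP43_KD and rose in TDP43_DCPS_KD, against 1212 for independent calls, and 2151 rose and then fell, against 1230. Genes that fell both times numbered 779, against 1187 for independent calls, and genes that rose both times 661, against 1256. Across all 18881 genes both steps correlated at r = -0.37, against -0.48 when the shared libraries alone were simulated without any effect, and their covariance was -0.184 against a simulated -0.0257. Part of the excess may come from the shared TDP43_KD libraries. Genes are not independent replicates in these correlations.

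**Figure D3:**
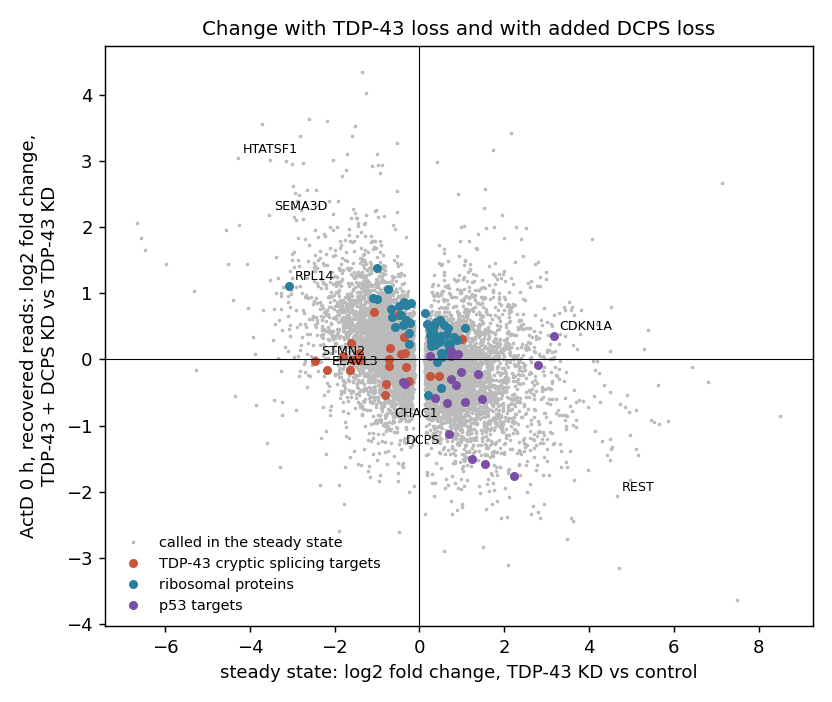
Log2 fold change in the steady state, TDP43_KD against control, and in the separate 0 h libraries, TDP43_DCPS_KD against TDP43_KD on recovered reads, with 1 point per gene called in the steady state and 3 lists coloured. Of 11022 genes, 67.1% have opposite signs on both axes.

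The third comparison set the double knockdown against control. STMN2 at -2.35 and ELAVL3 at -2.28 (log2) were still lower than in control. Of 18881 genes 11062 passed in edgeR (5547 higher, 5515 lower), 3528 of them by 2-fold or more (2103 higher, 1425 lower). The largest rises included MVP (4.68), COL9A2 (4.65), EHD2 (4.22), ADGRG5 (4.11), the transcription factor ETV1 (ENSG00000006468.14, 3.97 ± 0.07, from 14.3 ± 0.847 to 224 ± 13.6 CPM), CDKN1A (3.74) and COL9A3 (3.27). The largest falls were in H2AC6 (-5.81), GALR1 (-5.52), H3C6 (-5.00), the receptor phosphatase PTPRT (ENSG00000196090.12, -4.99 ± 0.12, from 71.8 ± 8.30 to 2.27 ± 0.366 CPM), TNR (-4.27), NELL1 (-3.84), CD36 (-3.47) and TMEM158 (-3.36).

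Of 75 ribosomal protein genes 62 rose and 4 fell (median 0.58, camera adjusted p = 1.31e-12, 0.484 with an estimated correlation), with RPLP0 at 1.18 but RPL14 at -2.37. Of 25 cryptic splicing targets 19 fell and 3 rose (median -0.43, adjusted p = 1e-11, 0.235 with an estimated correlation). Of 25 long-lived mRNAs 16 fell and 9 rose (adjusted p = 0.000458, 0.235 with an estimated correlation), with the calmodulin genes CALM2 at -1.64 and CALM3 at -1.55. Of 21 p53 targets 14 rose and 2 fell (adjusted p = 0.00209, 0.235 with an estimated correlation), and of 34 synaptic vesicle genes 20 fell and 7 rose (adjusted p = 0.00339, 0.235 with an estimated correlation). Cytoskeleton genes (16 of 28 lower, 5 higher, adjusted p = 0.00783, 0.484 with an estimated correlation), mitochondrially encoded mRNAs (11 of 13 lower, adjusted p = 0.0098, 0.636 with an estimated correlation) and glycolysis genes (11 of 19 lower, 7 higher, adjusted p = 0.0351, 0.484 with an estimated correlation) also passed. Adjusted over the list alone, 64 ribosomal protein genes rose, 15 p53 targets rose and 3 fell, 21 synaptic vesicle genes and 12 glycolysis genes fell, and the other counts of these lists were unchanged. With an estimated correlation none of 27 lists passed (4 with an unadjusted p under 0.05). Of 25 P-body and decapping genes 9 fell and 8 rose (adjusted p = 0.677), with EDC3 at -0.99 and DDX6 at -0.85.

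The 0 h libraries of the decay experiment gave the same comparisons in other libraries. On the deposited scale the whole distribution was lower in TDP43_KD, with column sums of 152921 ± 26842 (SD) in control, 82568 ± 7208 in TDP43_KD and 119126 ± 16166 in TDP43_DCPS_KD. The log2 difference of sums was -0.88 for TDP43_KD against control and 0.52 for TDP43_DCPS_KD against TDP43_KD (exact permutation p = 0.10 each, the smallest that 3 against 3 allow), and -0.35 for TDP43_DCPS_KD against control (p = 0.20). Of 1630 genes with a mean of at least 10, limma called 885 in TDP43_KD against control (40 higher, 845 lower), 795 in TDP43_DCPS_KD against TDP43_KD (758 higher, 37 lower) and 526 in TDP43_DCPS_KD against control (176 higher, 350 lower). Without TDP43_DCPS_KD replicate 3 the count of 795 was 478, and without control replicate 1 the count of 526 was 654 with the majority turned (400 higher, 254 lower). The median of all genes shifted by -0.52, 0.48 and -0.09 log2 in these comparisons. With quantile normalization the shares higher among called genes were 55.0%, 49.4% and 52.4%, against 4.52%, 95.3% and 33.5% on the deposited scale. Quantile normalization gives every library the same distribution, which removes a shift of all genes by construction. It therefore cannot decide whether the shift on the deposited scale was a change in total mRNA.

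Relative to the other genes, mitochondrially encoded mRNAs (13 of 13 lower, adjusted p = 0.000156, 0.977 with an estimated correlation) and cryptic splicing targets (7 of 10 lower, adjusted p = 0.0148, 0.977 with an estimated correlation) were lower in TDP43_KD than in control at 0 h. Without control replicate 2, which held 6.92% mitochondrial reads against 3.75% and 3.99% in the other control libraries, the mitochondrial list still passed (13 of 13 lower, adjusted p = 0.00555, 0.975 with an estimated correlation). The counts of members are on the deposited scale with its shift of all genes, where STMN2 stood at -3.40 log2 and ELAVL3 at -2.94. Ribosomal protein genes (62 of 65 higher, adjusted p = 2.38e-10, 0.957 with an estimated correlation) and cholesterol synthesis genes (11 of 15 higher, adjusted p = 0.0088, 0.957 with an estimated correlation) were higher in TDP43_DCPS_KD than in TDP43_KD. Against control, TDP43_DCPS_KD had higher ribosomal protein genes (44 of 65, adjusted p = 7.7e-14) and lower mitochondrially encoded mRNAs (13 of 13, adjusted p = 0.000104), cryptic splicing targets (5 of 10, adjusted p = 0.0002) and synaptic vesicle genes (8 of 17, adjusted p = 0.0178), each 0.997 with an estimated correlation. Without that control library the mitochondrial list was at an adjusted p of 0.00971 (9 of 13 lower).

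On recovered reads, an analysis added after the data were seen, edgeR called 8860 of 16556 genes in TDP43_KD against control (4498 higher, 4362 lower), 5288 in TDP43_DCPS_KD against TDP43_KD (2714 higher, 2574 lower) and 7862 in TDP43_DCPS_KD against control (3957 higher, 3905 lower). Fold changes correlated with those of the steady state at r = 0.88, 0.81 and 0.85 across 16521 genes, and 94.8%, 96.8% and 93.2% of steady-state calls kept their sign. REST stood at 5.05, MVP at 4.95, H2AC6 at -5.84 and STMN2 at -2.45 in TDP43_KD against control, and ECEL1 at 2.55, PABPC1 at 1.47 and ADAM12 at -2.90 in TDP43_DCPS_KD against TDP43_KD. TARDBP was at -3.02 in TDP43_KD against control and DCPS at -1.36 in TDP43_DCPS_KD against TDP43_KD. One control library at 0 h, replicate 2, had 6.92% of its reads from mitochondrial genes (group mean 4.89 ± 1.76%, SD), against group means of 3.81 to 4.56% in the other 11 groups.

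At 0 h on recovered reads camera called 11, 5 and 10 of 27 lists in the 3 comparisons, against 8, 7 and 8 in the steady state. With an estimated correlation it called 1, 0 and 0 of them at 0 h. Of 21 p53 targets 18 rose and 2 fell in TDP43_KD against control (median 1.22, adjusted p = 7.83e-10, 0.00915 with an estimated correlation). Of 25 genes of the integrated stress and unfolded protein response 18 rose and 2 fell (median 0.74, adjusted p = 7.96e-06, 0.357 with an estimated correlation), where 8 had risen and 7 fallen in the steady state. Cholesterol synthesis genes fell in TDP43_KD (12 of 24, 3 rising, adjusted p = 0.00357, 0.357 with an estimated correlation) and rose in TDP43_DCPS_KD against TDP43_KD (14 of 24, adjusted p = 1.93e-05, 0.393 with an estimated correlation). Ribosomal protein genes rose in that comparison too (55 of 74, 2 falling, median 0.46, adjusted p = 1.56e-15, 0.81 with an estimated correlation), while p53 targets (10 of 21, adjusted p = 0.00122, 0.157 with an estimated correlation) and stress response genes (10 of 25, adjusted p = 0.00268, 0.81 with an estimated correlation) fell.

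Actinomycin D stops new transcription, so the fall of a transcript over 6 h measures its decay. On the deposited scale most genes fell. In control MT-ND2 fell by 0.48 log2 per h and MT-ND1 by 0.40, and ELAVL2, a neuronal RNA-binding protein gene, by 0.60. The median slope of 1224 genes with a mean of at least 10 was -0.0976 log2 per h in control (a half-life of 10.2 h), -0.0862 in TDP43_KD (11.6 h) and -0.0325 in TDP43_DCPS_KD (30.8 h). These half-lives belong to that scale, whose constant and power differ between libraries. In the same order the medians were -0.0745, -0.0693 and 0.00648 with a mean of at least 50. With a pseudocount of 5 they were -0.0827, -0.067 and -0.0275, so the half-lives also depend on the value added before the log2. They were 0.0146, 0.0136 and 0.0168 with quantile normalization, and -0.0161, 0.0207 and 0.0222 when scaled to the long-lived list. Both of these settings remove a fall shared by all genes by construction. A positive median gives no half-life. The slope of the library medians differed by 0.0167 per h between TDP43_KD and control (exact permutation p = 0.825, 400 arrangements). The difference was 0.0478 between TDP43_DCPS_KD and TDP43_KD (exact permutation p = 0.52) and 0.0645 between TDP43_DCPS_KD and control (exact permutation p = 0.075). None passed, but these arrangements exchanged labels within time points, which turns differences in level between genotypes into slopes. They therefore cannot decide whether the overall slope differed between genotypes. Column sums at 6 h were 74787 ± 3653 in control, 47577 ± 9742 in TDP43_KD and 87748 ± 10317 in TDP43_DCPS_KD (SD, n = 3).

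Slopes of 902 genes differed from 0 in control (901 falling), of 810 in TDP43_KD (all falling) and of 389 in TDP43_DCPS_KD (388 falling). On the deposited scale the 13 mitochondrially encoded mRNAs fell faster than other genes in control (median -0.29 per h, camera adjusted p = 8.67e-06, 0.833 with an estimated correlation, and 0.00857 without control replicate 2 at 0 h) and in TDP43_KD (adjusted p = 0.00119, 0.962 with an estimated correlation). On recovered reads that difference was not found. The list's median slope was 0.02 per h in control (1 of 13 higher, 2 lower, adjusted p = 0.877), 0.01 in TDP43_KD (4 higher, adjusted p = 0.325) and 0.05 in TDP43_DCPS_KD (6 higher, adjusted p = 0.147). The 3 short-lived mRNAs measured, ID4, SOX4 and SOX11, fell faster in all 3 genotypes (adjusted p = 0.0014, 0.00321 and 7.79e-05, against 0.513, 0.593 and 0.142 with an estimated correlation), and the 4 stress response genes did in control (adjusted p = 0.0357, 0.833 with an estimated correlation). Ribosomal protein genes fell more slowly than others in control (20 of 65 falling, median -0.05, adjusted p = 6.65e-09, 0.965 with an estimated correlation) and in TDP43_DCPS_KD (adjusted p = 0.000109, 0.943 with an estimated correlation). In control the respiratory chain (adjusted p = 0.0266) and glycolysis genes (adjusted p = 0.0419) also stood above others in slope, each 0.965 with an estimated correlation.

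**Figure D4:**
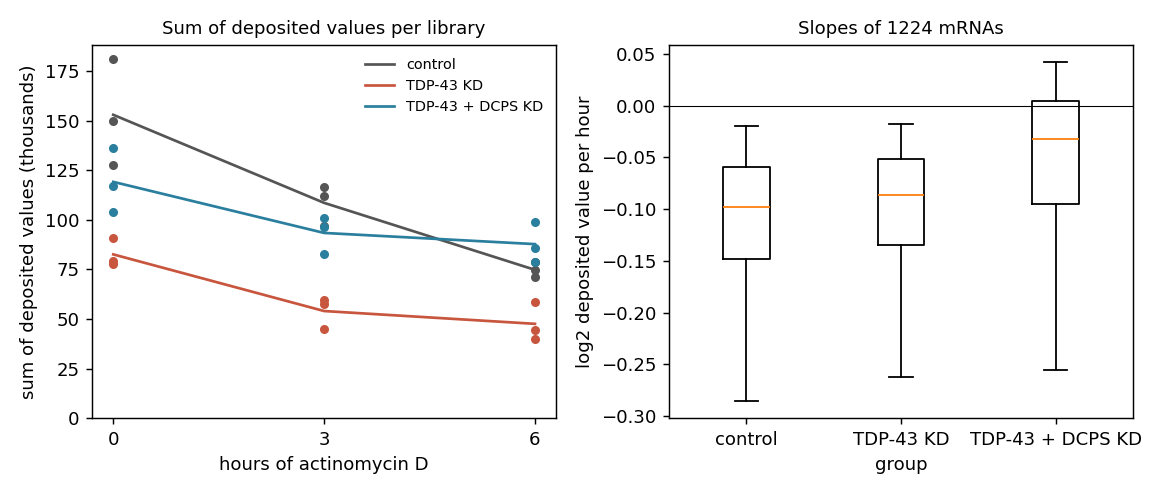
Left, sum of the deposited values of each library at 0, 3 and 6 h of actinomycin D, by genotype, with points for libraries and lines for the group means. Right, slopes of 1224 genes in each genotype, with boxes for the median and quartiles and whiskers to the 5th and 95th percentiles. Median slopes across genes were -0.0976 per h in control, -0.0862 in TDP43_KD and -0.0325 in TDP43_DCPS_KD.

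On recovered reads slopes are relative to the other genes, and 9529 of 17393 differed from 0 in control (4671 relatively stable, 4858 relatively unstable), 9400 in TDP43_KD (4046 and 5354) and 9778 in TDP43_DCPS_KD (4436 and 5342). With quantile normalization of the deposited values, too, 61.4%, 58.8% and 59.5% of called slopes were positive, and on recovered reads 49.02%, 43.04% and 45.37%. Both remove a fall shared by all genes by construction, so directions of slopes there are relative to other genes. The steepest relative falls in control were those of TXNIP (-1.55 per h), the phosphatase genes DUSP1 (-1.49) and DUSP6 (-1.25), CITED2 (-1.49), TIPARP (-1.30) and ZNF703 (-1.21), and the most stable were PDIA2 (0.40), PPP1R14A (0.39), CDK5RAP3 (0.38) and SNHG19 (0.36). Of 21 short-lived mRNAs 17 were unstable (median -0.72, adjusted p = 1.68e-06) and of 15 immediate-early genes 12 were (median -0.57, adjusted p = 0.000177), while 72 of 74 ribosomal protein genes (median 0.20, adjusted p = 1.81e-21) and 24 of 25 long-lived mRNAs (adjusted p = 6.62e-12) were relatively stable, each 0.248 with an estimated correlation.

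The last comparisons asked whether decay differed between genotypes. On recovered reads 1801 slopes differed between TDP43_KD and control (711 slower, 1090 faster to fall in TDP43_KD). HSP90B1, an endoplasmic reticulum chaperone, decayed faster in TDP43_KD (difference -0.70 ± 0.04 SE per h), as did MAGEE1 (-0.72 ± 0.05), the antisense transcript NCAM1-AS1 (-0.66 ± 0.11), VTA1, of the endosomal sorting machinery (-0.63 ± 0.06), DRGX (-0.63 ± 0.09), KBTBD6 (-0.61 ± 0.05) and the P-body helicase gene DDX6 (-0.37 ± 0.04). TARDBP itself, the target of the shRNA, was at -0.20 ± 0.04 (edgeR adjusted p = 0.00232). For this gene an effect of the shRNA on its mRNA cannot be told apart from an effect of TDP-43 loss. DUSP1 (0.67 ± 0.21), LIN28A (0.62 ± 0.10), the kinase gene PIM1 (0.57 ± 0.10), the receptor gene FZD1 (0.49 ± 0.09), SCRT2 (0.49 ± 0.05) and MFHAS1 (0.46 ± 0.05) decayed more slowly. The edgeR adjusted p of these genes ran from 1.47e-13 for HSP90B1 to 0.0386 for DUSP1.

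Slopes of ribosomal protein genes (7 of 74 faster, median -0.06, adjusted p = 3.97e-05), cytoskeleton genes (6 of 28 faster, adjusted p = 0.00054), respiratory chain genes (4 of 34, adjusted p = 0.00122), long-lived mRNAs (4 of 25, adjusted p = 0.00142) and synaptic vesicle genes (5 of 33, adjusted p = 0.038) were lower in TDP43_KD than those of other genes, each 0.787 with an estimated correlation. Among them were RPL14 (-0.29 ± 0.04), RPL9 (-0.35 ± 0.05), SPTAN1 (-0.18 ± 0.03) and ERC2 (-0.23 ± 0.04). Of 25 P-body and decapping genes 3 were slower and 3 faster (adjusted p = 0.845). Limma called 23 of 1224 slope differences on the deposited scale (10 slower, 13 faster), among them MT-TC (0.19 ± 0.05 per h), ATF4 (0.16 ± 0.05), RPL7 (-0.19 ± 0.05) and RPL10 (-0.16 ± 0.04). This count ran from 8 to 48 as single libraries were left out (39 slower and 9 faster without control 0 h replicate 2), was 3 with a pseudocount of 5 and 400 (362 slower, 38 faster) when scaled to the long-lived list. The ribosomal (adjusted p = 1.66e-06), long-lived (0.019), respiratory chain (0.0198), stress response (0.0347) and glycolysis lists (0.0347) passed there, each 0.924 with an estimated correlation.

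Between TDP43_DCPS_KD and TDP43_KD 685 slopes differed on recovered reads (242 slower, 443 faster in the double knockdown). HTATSF1 (0.52 ± 0.04), HSPA13 (0.42 ± 0.08), BZW2 (0.38 ± 0.05) and DRGX (0.37 ± 0.10) decayed more slowly. CHAC1, a stress-induced enzyme of glutathione breakdown (-0.62 ± 0.15), CHST8 (-0.56 ± 0.06), SCRT2 (-0.48 ± 0.05), ZNF30 (-0.48 ± 0.06), TNFRSF21 (-0.48 ± 0.03), HS6ST1 (-0.47 ± 0.03) and the decapping coactivator gene PNRC2 (-0.32 ± 0.06) decayed faster, as did the p53 targets PHLDA3 (-0.43 ± 0.05) and BBC3 (-0.44 ± 0.06). Short-lived mRNAs were lower as a list (median -0.15, adjusted p = 0.0194, 0.936 with an estimated correlation), with 1 of 21, ID4 (-0.26 ± 0.03), past the test by itself. Of deposited slopes 19 differed (10 slower, 9 faster), with RPL4 (0.21 ± 0.04), RPL10 (0.18 ± 0.04) and RPS6 (0.16 ± 0.04) slower and ID4 (-0.23 ± 0.04) faster. That count ran from 13 to 30 as single libraries were left out, and was 5 with a pseudocount of 5, 66 (29 slower, 37 faster) with quantile normalization and 79 (22 slower, 57 faster) when scaled to the long-lived list. The ribosomal list (3 of 65 slower, 8 over the list alone, adjusted p = 0.000321, 0.956 with an estimated correlation) and short-lived list (adjusted p = 2.16e-05, 0.0966 with an estimated correlation) passed.

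Between TDP43_DCPS_KD and control 1436 slopes differed on recovered reads (519 slower, 917 faster). LIN28A (0.63 ± 0.10), MFHAS1 (0.51 ± 0.05) and C2orf69 (0.43 ± 0.04) decayed more slowly, and CHAC1 (-0.76 ± 0.16), ATF3 (-0.67 ± 0.15), VTA1 (-0.65 ± 0.07), KCTD2 (-0.63 ± 0.03), MAGEE1 (-0.61 ± 0.05) and HSP90B1 (-0.51 ± 0.04) faster. Long-lived mRNAs (6 of 25 faster, adjusted p = 0.00245), ribosomal protein genes (1 of 74, adjusted p = 0.0313) and cap genes (4 of 16, adjusted p = 0.0313) had lower slopes, each 0.98 with an estimated correlation. On the deposited scale 119 slopes differed (96 slower, 23 faster), with MT-TC (0.29 ± 0.05), MT-ND2 (0.25 ± 0.05) and KIF5A (0.13 ± 0.04) slower and TUBA1B (-0.20 ± 0.05) faster, and the mitochondrially encoded list was higher (10 of 13, adjusted p = 0.0014, 0.996 with an estimated correlation). Without the control 0 h library with 6.92% mitochondrial reads the list did not pass (camera adjusted p = 0.859). Its median difference was then 0.17 per h (0.20 with that library) and 10 of 13 genes passed, but calls among all genes rose from 119 to 538. On recovered reads the mitochondrially encoded list was not among those that passed camera for this slope difference. As single libraries were left out the count of 119 ran from 23 to 538, and with quantile normalization it split into 95 slower and 66 faster. On recovered reads the slope differences of both steps correlated at r = -0.46, against -0.50 expected from the shared TDP43_KD libraries alone, so no movement back of slopes was read from it.

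Whether decay differences went with abundance was asked across genes, with fold changes from the steady-state libraries and slopes from the decay libraries. In TDP43_KD against control r was 0.24 on the deposited scale (1224 genes) and 0.22 on recovered reads (17265 genes, Spearman 0.25). Of 1090 genes that decayed faster in TDP43_KD, 883 were called lower in its steady state, and of 710 that decayed more slowly, 457 were called higher. The same r was 0.43 and 0.21 in TDP43_DCPS_KD against TDP43_KD and 0.35 and 0.20 in TDP43_DCPS_KD against control, 6 correlations in all, given as description since genes are not independent replicates. With a mean of at least 50 the first was -0.04 over 215 genes.

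**Figure D5:**
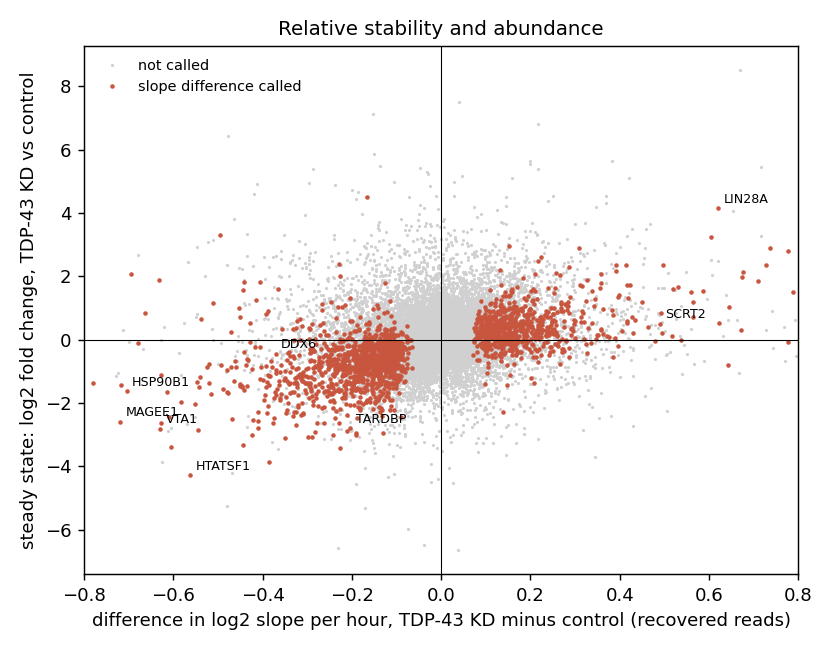
Steady-state log2 fold change of TDP43_KD against control and the difference in slope under actinomycin D in log2 per h, with 1 point per gene on recovered reads and called slope differences marked, drawn from -0.8 to 0.8 per h. Pearson r is 0.22 across 17265 genes.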

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

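The splits of the libraries, the tests of the deposited scale and the test with separate libraries were chosen after the results were seen. The tests of a milder TDP-43 loss, of a common share of return, of length and abundance trends and of pseudogenes were fixed before theirs.

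The decay slopes differed between genotypes by a direct test of the difference. On the deposited scale 23 genes differed between TDP43_KD and control, 19 between TDP43_DCPS_KD and TDP43_KD and 119 between TDP43_DCPS_KD and control. On recovered reads 1801, 685 and 1436 did. In fits of the 2 genotypes alone, with labels exchanged within time points, the splits of the deposited values gave the following. For TDP43_KD minus control 4 of 100 splits called as many as the real 3 genes (highest other 675). The 2 largest of the others, 675 and 672, exchanged the genotypes at a whole time point, which by construction turns differences in level into slopes. That share is under 0.05, but the real count is 3, so chance is left open. In simulated data without differences in scale between libraries the same test called 2 unchanged genes. For TDP43_DCPS_KD minus TDP43_KD 5 of 100 called as many (real 28, highest other 703), and for TDP43_DCPS_KD minus control 5 of 100 (real 154, highest other 609). In these last 2 comparisons the other splits as large exchanged 1 or 2 of 3 libraries at 0 h and none at 6 h. That also carries part of the differences in level into slopes. Such splits therefore cannot decide on chance in any of these comparisons, and it is left open.

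On recovered reads 1 of 40 splits, the real one, called as many for TDP43_KD minus control (real 1487, highest other 1). The same held for TDP43_DCPS_KD minus TDP43_KD (real 740, highest other 0). For TDP43_DCPS_KD minus control 2 of 40 splits called as many (real 1499, highest other 8177). That other split exchanged the genotypes at all of 0 h, so it is no test of chance. Exchanging only part of the labels moves differences in level between genotypes into the spread within groups, which lowers the calls of other splits. These splits therefore cannot decide on chance in any of these comparisons, and the question is left open. Of the 12 other splits as large in all these tests, 3 exchanged a whole time point.

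A first pattern was the lower level of TDP43_KD on the deposited scale at 0 h, a log2 difference of sums of -0.878. With the power of the deposited values set to 1 and the deposited sums kept, the median difference was -0.636, against -0.52 before. Since the sums themselves were kept, this cannot decide whether the power gave their difference. Sequencing depth was higher, not lower, in TDP43_KD (log2 difference 0.183 ± 0.140 SE). The deposited sum per read per base, in which the constant and the power of each library enter together, differed by -1.05 log2. The source of both is not given in the sources used here. A processing step and a loss of total mRNA in these neurons therefore cannot be told apart.

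A second pattern was that changes of TDP43_KD moved back in TDP43_DCPS_KD. Shared libraries are argued against by the separate 0 h libraries, where 3136 of 4105 genes called in both (76.4%) had opposite signs. For the 10 cryptic splicing targets called at 2-fold or more, the median share of return was -0.00389 (resampled SD 0.0401), against 0.233 for all 3329 such genes. That argues against a milder TDP-43 loss for these targets only. Across the whole list in the steady state, the median fall from control was smaller in the double knockdown, where more members rose than fell against TDP43_KD. TARDBP mRNA was also slightly higher there, and gene totals measure neither splicing nor TDP-43 protein. A partly milder loss therefore stays open. A common share of return given by TARDBP (0.0795) is argued against by the 48.2% of genes that moved back by more than 0.25. After removing trends on gene length and abundance 67.7% were opposite, against 67.1% before. With shared libraries and trends on length and abundance argued against, a candidate explanation is an effect of DCPS knockdown on these transcripts. It is a hypothesis found and tested on the same data. A partly milder TDP-43 loss was not ruled out, and an effect of the second shRNA on other targets stays untested.

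The last pattern was the higher level of ribosomal protein mRNAs in TDP43_DCPS_KD than in TDP43_KD. After removal of length and abundance trends their median was 0.43 against 0.39 before, above the 0.16 that the highest of the matched gene lists reached. The 37 genes with fewer than 14 named pseudogenes had a median of 0.40 (0.395) and the others 0.39. The number of named pseudogenes and the log2 difference had a Spearman correlation of 0.00728. These values argue against a rise that grows with the number of pseudogenes. No ribosomal protein gene tested was without a named pseudogene, so reads shared with pseudogenes were not ruled out. Depth differed by -0.137 log2 between these groups. A rise of the class with DCPS knockdown may be a biological change, as a hypothesis, but the list's call is lost with an estimated correlation, so a factor common to these genes and differing between the libraries was not ruled out.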

How the results depend on the processing

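Of the alternatives, recovered reads, a power of 1 and the mitochondrial list without control 0 h replicate 2 were chosen after the data were seen. DESeq2 was not run on the deposited decay values. Steady-state counts stayed within 1.5 times with other size factors, no filter, a mean of at least 50, DESeq2 and the 2 groups alone, from 9693 to 11910, 7145 to 8623 and 9238 to 11094, and only a minimum of 2-fold moved them, to 4044, 1293 and 3528, by construction. The cause of the other moves was not tested, except that a mean of at least 50, no filter and a minimum effect change the number tested or called by construction. Values follow the order TDP43_KD against control, TDP43_DCPS_KD against TDP43_KD, TDP43_DCPS_KD against control.

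At 0 h the counts of 885, 795 and 526 became 4140, 1745 and 2440 with no filter, 148, 160 and 113 with a mean of at least 50, 409, 191 and 183 at 2-fold, 8860, 5288 and 7862 with edgeR on recovered reads and 8587, 5153 and 7601 with DESeq2 on them. Quantile normalization moved the last to 1028 and a power of 1 the first to 1406. Slopes that differed from 0 in control, TDP43_KD and TDP43_DCPS_KD (902, 810 and 389) became 13380, 10010 and 13392 with no filter, 113, 109 and 26 with a mean of at least 50, 9529, 9400 and 9778 with edgeR and 9683, 9640 and 9950 with DESeq2 on recovered reads. Scaling to the housekeeping list gave 590 in control and 763 in TDP43_DCPS_KD, quantile normalization 723 in TDP43_DCPS_KD, and a minimum of 0.1 per h 591 in control and 487 in TDP43_KD.

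Slope differences of 23, 19 and 119 genes became 100, 55 and 216 with no filter, 2, 1 and 27 with a mean of at least 50, 3, 5 and 72 with a pseudocount of 5, 400, 79 and 383 with the housekeeping list, 1801, 685 and 1436 with edgeR and 2047, 943 and 1762 with DESeq2 on recovered reads. Quantile normalization gave 190 for TDP43_KD minus control and 66 for TDP43_DCPS_KD minus TDP43_KD. A power of 1 gave 39 for TDP43_KD minus control and 453 for TDP43_DCPS_KD minus control, and 6 h against 0 h gave 78 for the latter. Of called slope differences 43.5%, 52.6% and 80.7% were positive, against 49.5%, 43.9% and 59.0% with quantile normalization, 90.5%, 27.85% and 85.6% with the housekeeping list and 39.5%, 35.3% and 36.1% on recovered reads.

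The correlation of abundance and slope difference (0.237) reversed to -0.0430 with a mean of at least 50, over fewer genes, and was 0.428 for TDP43_DCPS_KD against TDP43_KD in its place and 0.358 with a power of 1. The share moving back (62.6%) was 62.5 to 72.0% under its other settings. Calls of gene lists, 3 contrasts added, fell from 23 in the steady state, 8 at 0 h, 10 for slopes and 9 for slope differences to 0 each with an estimated correlation (camera), where 9, 0, 3 and 1 tests had an unadjusted p under 0.05.

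Leaving out each library in turn gave 10961 to 11815, 6756 to 8432 and 10200 to 11047 in the steady state, 742 to 985, 478 to 980 and 388 to 654 at 0 h, 630 to 1077, 587 to 1018 and 286 to 454 for slopes, and 8 to 48, 13 to 30 and 23 to 538 for slope differences. The share moving back was 60.8 to 64.7%, the correlation 0.199 to 0.265, and list calls 22 to 32, 8 to 12, 5 to 11 and 2 to 12. At 0 h the 478 came without TDP43_DCPS_KD replicate 3. For TDP43_KD minus control the count was 48 without control 0 h replicate 2, 14 and 12 without control 6 h replicates 2 and 3, 8 and 15 without TDP43_KD 0 h replicates 2 and 3, 46 without TDP43_KD 3 h replicate 2, 10, 12 and 12 without TDP43_KD 6 h replicates 1, 2 and 3, and 15 without TDP43_DCPS_KD 0 h replicate 2. For TDP43_DCPS_KD minus TDP43_KD it was 29 without control 0 h replicate 2 and 30 without TDP43_KD 3 h replicate 2. For TDP43_DCPS_KD minus control it was 60, 538 and 259 without control 0 h replicates 1, 2 and 3, 38, 33 and 46 without those at 6 h, 228 without TDP43_KD 3 h replicate 2, 180 without TDP43_KD 6 h replicate 1, 47, 69 and 282 without TDP43_DCPS_KD 0 h replicates 1, 2 and 3, and 23, 31 and 65 without those at 6 h. List calls fell to 5, 6 and 6 for slopes without control 0 h replicates 2 and 3 and TDP43_DCPS_KD 0 h replicate 2, and to 2 for slope differences without control 0 h replicate 2. Without control 0 h replicate 2 the mitochondrial list lost its call in the slope difference of TDP43_DCPS_KD minus control (adjusted p 0.859, median 0.17 against 0.20, 10 of 13 genes higher in both) and kept it at 0 h. On recovered reads slope differences kept within 1446 to 2027, 473 to 785 and 1137 to 1646.

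The labels do not say that a replicate number marks a shared culture or day. Residuals of libraries of equal number correlated at -0.05 to 0.09 in the steady state, and at 0 h 3 of 9 such pairs exceeded 0.1 (up to 0.179, against at most 0.073 for other pairs). The numbers were therefore not taken as pairs, and a shared batch at 0 h stays open. With a replicate block the counts were 11860, 8037 and 11181 in the steady state, 784, 644 and 413 at 0 h, 931, 840 and 403 for slopes, 25, 22 and 175 for slope differences, and 23, 9, 10 and 9 for lists.

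Counted as pairs of a named gene and an alternative, a call was lost in 19 pairs in the steady state, 98 at 0 h on recovered reads, 191 for deposited slopes and 305 for slopes on recovered reads, and no sign turned except where the scale was centred anew. There, 28 of 146 deposited slopes turned sign with quantile normalization, 11 with the housekeeping list, 89 with edgeR and 98 with DESeq2 on recovered reads, and 23 of 272 slopes on recovered reads did with the housekeeping list, while no named slope difference turned. Calls were lost, however. Of 24 named deposited slope differences 10 lost their call with quantile normalization, 1 with the housekeeping list, 14 with edgeR and 9 with DESeq2 on recovered reads. Of 173 named slope differences on recovered reads 42 did with the housekeeping list. At 6.93 to 11.8 M reads, genes under about 10 on the deposited scale were not tested for decay there. Slope differences that reached 1.5-fold in level at 6 h were found in 35% of simulated genes. A 1.5-fold change of the decay rate itself was not simulated.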

Other observations

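The test of decay against abundance, and the splits given here, were chosen after the results were seen. In TDP43_KD the steepest relative falls belonged to TIPARP (-1.14 per h), CITED2 (-1.07), RND3 (-0.97), RNF139 (-0.92), ZNF703 (-0.90) and CHAC1 (-0.86), and in TDP43_DCPS_KD to CHAC1 (-1.48), DUSP1 (-1.40), TXNIP (-1.28), CITED2 (-1.25), RND3 (-1.17) and EFNB2 (-1.06). Among the 6 most stable of either genotype, 4 were shared, PDIA2 (0.36 and 0.40), YJEFN3 (0.45 and 0.37), AMH (0.39 and 0.37) and MAN2C1 (0.29 and 0.36). Single transcripts of decay factors with small p-values in control were PELO, a ribosome rescue factor, at -1.01 per h, BTG1, an antiproliferative deadenylation factor, at -0.81, SMG8 at -0.69 and PNRC2 at -0.44. Of 20 deadenylation genes 13 were relatively unstable and 3 stable in control (camera adjusted p = 0.037, 0.248 with an estimated correlation), while the lists of P-body and decapping (13 of 25 unstable, 6 stable, adjusted p = 0.147), exosome (6 and 6 of 20, adjusted p = 0.635) and nonsense-mediated decay genes (7 and 4 of 15, adjusted p = 0.635) did not pass.

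Of 27 postsynaptic genes 10 rose and 8 fell in the double knockdown against TDP43_KD (camera adjusted p = 0.549), so single genes are named here without a common direction. GRIN2A, an NMDA receptor subunit, went from 101 ± 8.36 CPM in TDP43_KD to 26.8 ± 1.42 CPM (log2 -1.91 ± 0.07 SE), and GRIA2, an AMPA receptor subunit, from 62.6 ± 1.53 to 150 ± 5.06 CPM (1.26 ± 0.07), against 50.2 ± 3.20 and 30.1 ± 4.03 CPM in control (SD, n = 3). The vesicle genes CPLX2 (-1.64 ± 0.05) and SYT2 (-1.12 ± 0.08) fell while SLC17A6 (0.64 ± 0.06) and SLC17A7 (0.56 ± 0.05) rose. CALM2 went from 1191 ± 30.9 to 369 ± 10.6 CPM (-1.69 ± 0.05), while EEF1A1, a translation elongation factor gene, rose from 7585 ± 285 to 12186 ± 697 CPM (0.68 ± 0.05).

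A hypothesis was that transcripts decaying faster in TDP43_KD are less abundant for that reason. Of 1090 genes with a faster relative fall, 964 (88.4%) were lower in the TDP43_KD steady state, against 48.7% of all genes and at most 55.7% in draws of genes matched for abundance. This is consistent with faster decay lowering abundance, but the same would hold if misprocessed transcripts were both fewer and less stable, which was not tested, and the r of 0.22 across all genes leaves most of the change in abundance unaccounted for.

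Other splits of the libraries gave the following for the remaining counts. The 10 splits of 6 libraries are too few for a share under 0.05. In the steady state, fitted with the 2 groups alone, the real counts were 11360, 8623 and 10565 and the highest others 1, 0 and 0. At 0 h they were 871, 941 and 481 with highest others of 0 on the deposited scale, and 8457, 6718 and 6859 with highest others of 1, 0 and 0 on recovered reads, the real split being the 1 with as many in each. For slopes fitted in a single genotype with the times exchanged, 3 of 100 splits called as many as the real 985 in control (highest other 1232). In TDP43_KD 2 of 100 called as many as 514 (highest other 520), and in TDP43_DCPS_KD 2 of 100 as many as 547 (highest other 577). These shares are under 0.05, which argues against chance. On recovered reads 1 of 40 splits, the real one, called as many in each genotype (8686, 9145 and 9987, highest others 6754, 3875 and 0). That argues against chance there too.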
